A study of Homo sapiens with 6 samples.

How the data were processed

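Total RNA of MDA-MB-231 cells, 3 control and 3 shikonin libraries, was extracted after Trizol lysis and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. How RNA was selected, and whether strand was kept, is not given in the sources used here. The control samples are labelled as having no treatment, and a vehicle is not given in the sources used here. The submitters' processing notes name fastp, HISAT2 2.0.5, DESeq2 and the hg38 build. The read counter and the gene annotation are not given in the sources used here.

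The authors' deposited table holds 1 comparison. Its mean normalized count is a signal averaged by the authors over all libraries after division by size factors, per the file headers. The log2 fold change and its standard error are the authors' values, per the file headers. Its Wald score is, per the file headers, the authors' fold change over its standard error, and was checked to equal that ratio in every listed gene. The p-value and its adjusted value are the authors', per the file headers, and the p-values recomputed from the score differed by at most 0.489%. Every listed gene had an adjusted p below 0.05 and a fold above 1.5, so unlisted genes were either not past these thresholds or not tested. The sign matched the authors' direction mark in all 7150 genes.

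The planned tests of counts or normalized values per sample, the gene set test with preset or estimated correlation, the block by replicate number, the leave-one-out fits, other splits of the samples and the comparison of replicates for duplicates could not be run, since the table holds no per-sample values. The substitutes below were chosen after the file was seen. Each of 30 gene lists (744 distinct symbols, of which 443 were listed), fixed before the data were examined, was tested by a two-sided Fisher exact test of higher against lower genes, members against all other listed genes. P-values were adjusted by Benjamini-Hochberg over the 26 lists with at least 5 listed members. This test takes genes as independent, which co-regulated genes are not, so its p-values are too small, and it does not see unlisted genes. A count adjusted over the list alone could not be given, because p-values of unlisted genes are not held.

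Lists were also compared with 10000 draws of listed protein-coding genes matched by deciles of genomic span or mature transcript length. GENCODE 29 (GRCh38) gave positions, types and lengths for 7142 genes, matched by Ensembl identifier. Mature length was first taken from the longest APPRIS principal transcript. That choice gave wrong lengths for some genes, for example 1024 nt for AHNAK and 7686 nt for RPL37, so a second definition, the transcript with the longest coding sequence, was added after the first results were seen. The second can also give wrong lengths. Of the 8 lists called against all other listed genes, matching kept 6 with the first and 3 with the second. With the first it also called the mitochondrially encoded messages, toward lower. The median log2 fold change of each list was also compared with medians of 1000 draws of other listed protein-coding genes, a test added after the list results were seen. Draws were matched in 50 bins of mature length, or in its deciles by quintiles of the mean normalized count. Both definitions of length were used, over all listed genes and over those with implied means of at least 10 in both groups, which gives 8 matchings. P-values were adjusted by Benjamini-Hochberg over the lists in each matching. These draws, and those of the share, also take genes as independent, so their p-values are too small for co-regulated lists. The 8 matchings reuse largely the same genes and are not independent tests. Draws also hold genes that fell, which lowers their medians. For a list with every member higher, the size test therefore partly repeats the share. A list median above the highest draw in all 4 matchings over all listed genes was the bound first written for setting length aside. It was written for the ribosomal protein, respiratory chain, histone and luminal lists. Heat shock genes, for which it was not written, also met it, with implied means of at least 10 as well. After a first run in which the histones passed it, the version with implied means of at least 10 was added to the bound, and the histones no longer passed. That version was then taken out again, on the ground that an implied control mean is solved from the fold itself. Both versions are reported, and the histone result rests on this choice. The number of genes tested was recovered from adjusted p, rank and p. Implied group means were solved from the mean and the fold, assuming equal weight of 3 and 3 libraries. Fold intervals at 95% are normal intervals from the listed standard error, whose median was 0.192. The equal-totals alternative shifted every log2 fold change by 0.394, the log2 ratio of the implied totals.

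Named genes followed a rule set before the data were examined: the 6 most increased and 6 most decreased with a symbol and a mean of at least 1, the 3 members with the smallest p of each list with at least 3 listed members, and HMOX1 and PKM. Its condition that the groups do not overlap could not be applied. Up to 8 genes a side by fold (both implied means at least 10) or by p were added after seeing the values, and not all of the genes named by these rules are reported here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The scripts were tested on simulated data for this comparison: the number tested was recovered at 100% over 14000 genes. In 50 simulated tables of 7150 genes, 0 lists were called with random directions, and 70.3% of lists made 85% higher were called. With directions set by genomic span alone, a mean of 1.66 lists was called against all other genes and 0 against genes matched on span. No simulation of lists set directions by mature length, so matching on mature length was not checked in this way. Random directions were drawn for each gene independently, unlike those of co-regulated genes.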

Results

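RNA was sequenced from MDA-MB-231 cells, a human triple-negative breast cancer line that grows with a mesenchymal shape. The libraries were 3 from untreated control cells and 3 from cells given 0.5 µM shikonin, a naphthoquinone from the root of Lithospermum erythrorhizon, for 24 h. The dose is read as micromolar, since the labels write its unit with a lower-case m. The comparison asks which transcripts differed between treated and untreated cells. The file analysed here is the authors' deposited table of the genes past their thresholds, with 0 columns of per-sample values, so the depth of each library is unknown here. Its header does not name the group in the numerator: positive values carry the authors' mark "up" and are read throughout as higher in shikonin. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

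Shikonin-treated cells had much higher RNA of heat shock chaperones, of NRF2 target genes such as HMOX1 and of ATF4 pathway genes such as DDIT3, together with SNAI1, ID2 and the GADD45 genes. Genes with long transcripts, among them PLEC, FAT1, LNPEP and TAOK1, were lower. In the authors' deposited table a total of 7150 genes stood, 3630 higher and 3520 lower, at an adjusted p below 0.05 and a fold change above 1.5 by the authors' DESeq2 test. Of these, 4428 differed by at least 2-fold, 2341 higher and 2087 lower (52.9% higher), a split that became 1332 and 3432 (28.0% higher) with the implied totals of the listed genes set equal in both groups. Among genes with a mean of at least 100 normalized counts, 1579 were at least 2-fold higher and 1836 lower (46.2% higher). The 95% interval of the fold, taken from the listed standard error, lay wholly beyond 2-fold for 2235 genes, 1201 of them higher. Larger differences, with no minimum level set, lay mostly on the higher side: 338 genes were at least 8-fold higher and 39 at least 8-fold lower. Part of this imbalance may rest on genes near 0. An implied mean below 1 in a group was found for 168 listed genes, 153 of them higher and 15 lower. The adjusted p-values in the table imply about 14252 genes tested, with about 8712 past the adjusted p threshold, which is 61.1% of them. The balance of all listed genes depended on the scaling in the same way: with equal implied totals, 2181 genes were higher and 3520 lower, or 38.3% higher against 50.8% with the authors' scaling. Only higher genes could leave the count under that shift, since unlisted genes that would enter it as lower are not held.

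The HSPA6 gene, which encodes an inducible HSP70 chaperone, had the largest increase in the authors' deposited table, with a log2 fold change of 12.57 ± 0.42 (standard error) and an adjusted p of 6.25e-189. This is a 6074-fold difference (95% interval 3410 to 10817), from an implied mean of 24.0 normalized counts in control to 145959 in shikonin. HSPA6 has a single exon on chromosome 1, from 161524540 to 161526910 (GRCh38, GENCODE 29). DNAJB1, an HSP40 co-chaperone on chromosome 19 (14514770 to 14529770), was 27.4-fold higher (21.9 to 34.4) in the authors' deposited table. SNAI1, a transcription factor that represses E-cadherin, lies on chromosome 20 from 49982999 to 49988886 and was 162-fold higher (128 to 205), with its p listed as 0 in the authors' deposited table. ID2, an inhibitor of basic helix-loop-helix factors on chromosome 2 (8678845 to 8684453), was 213-fold higher (158 to 286) in the authors' deposited table. GADD45G and GADD45B, which encode stress-induced adaptor proteins, were 287-fold (136 to 606) and 35.5-fold (28.6 to 44.0) higher by the authors' deposited table. RGS2, a regulator of G-protein signalling, was 61.8-fold higher (49.1 to 77.8) in the authors' deposited table. GADD45G and RGS2 were named after their values were seen.

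**Figure D1:**
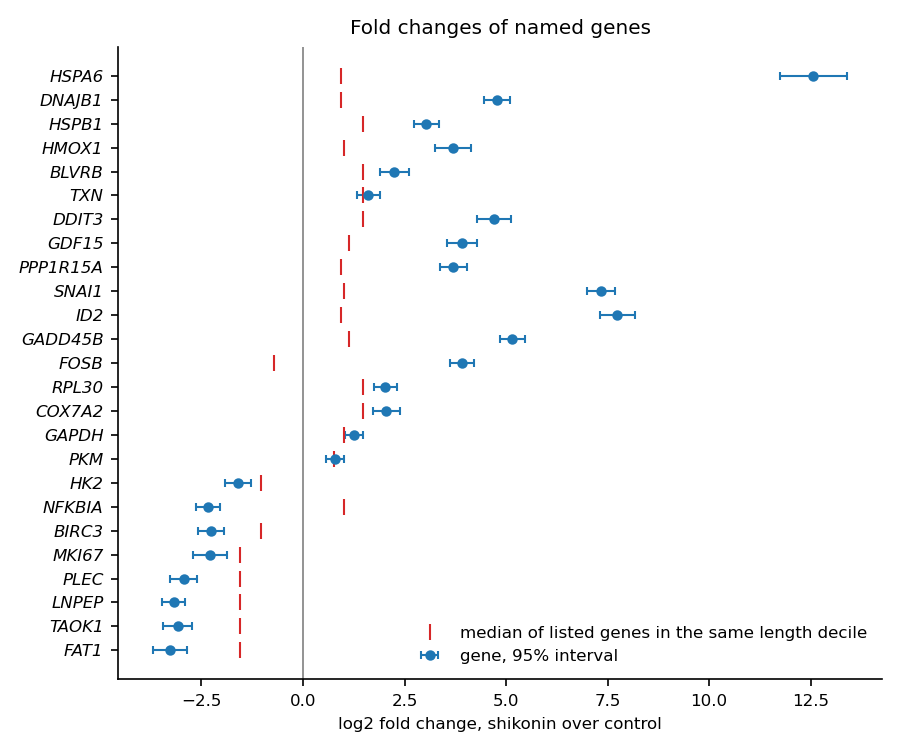
Log2 fold change of 25 named genes, shikonin over control, from the authors' deposited table (points), with 95% intervals from the listed standard errors (bars); red ticks give the median of the listed protein-coding genes in the same decile of mature transcript length. HSPA6 stands at 12.57 and PKM at 0.78, close to the median of its length decile.

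Genes of 3 stress programmes rose. Of 20 listed heat shock genes, 19 were higher and 1, HSPA4L, was lower (adjusted p = 2.11e-04, two-sided Fisher exact test against the other listed genes, Benjamini-Hochberg over 26 lists). HSPB1, a small heat shock protein gene, was 8.23-fold higher (6.60 to 10.3) in the authors' deposited table. HSPA1B was 22.8-fold higher (13.6 to 38.3) in the authors' deposited table, and is uncertain because its reads cannot be fully told from those of HSPA1A. All 18 listed NRF2 targets were higher (adjusted p = 6.71e-05), while 14 of the 32 in that list were not listed. Of all genes tested, 50.2% were listed. HMOX1, the heme oxygenase gene on chromosome 22 (35380361 to 35394214, 5 exons), was 13-fold higher (9.59 to 17.7; adjusted p = 2.35e-58) in the authors' deposited table. BLVRB, which encodes a biliverdin reductase, and TXN, which encodes thioredoxin, were 4.76-fold (3.72 to 6.09) and 3.05-fold (2.51 to 3.70) higher in the authors' deposited table. Of 26 listed genes of the ATF4 and amino acid response, 22 were higher and 4 lower (adjusted p = 0.00201). DDIT3, which encodes the factor CHOP, lies on chromosome 12 (57516588 to 57521737) and was 26.1-fold higher (19.5 to 34.9) in the authors' deposited table. GDF15, a secreted stress cytokine gene, and PPP1R15A, which encodes GADD34, were 15.1-fold (11.6 to 19.5) and 13-fold (10.3 to 16.4) higher in the authors' deposited table. The lower members were SLC7A1, SLC7A5, VLDLR and ASNS, of which the first pair encode amino acid transporters. By share higher against genes matched on mature transcript length, these 3 lists kept their calls under both definitions of the reference transcript that were run (adjusted p 0.00910 to 0.00988 with the principal transcript, 0.0130 to 0.0425 with the longest coding sequence). By the size of the median change against length-matched draws, NRF2 targets were past an adjusted p of 0.05 in 8 of 8 matchings (0.0130 to 0.0433), heat shock genes in 2 (0.0260 to 0.304) and ATF4 pathway genes in 0 (0.0891 to 0.251). These p-values by size are two-sided, so that draws with a negative median counted as far off as a rise. The heat shock median lay above the highest draw in all 8 matchings and the ATF4 median in most of them. The NRF2 median did so in few. The larger p-values of the heat shock and ATF4 lists therefore do not show that length accounts for their rise. By share, the heat shock call was lost against genes matched on genomic span (adjusted p = 0.0717).

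Genes of cytosolic ribosomal proteins and of the nuclear-encoded respiratory chain were higher too. All 49 listed cytosolic ribosomal protein genes were higher (adjusted p = 1.01e-13), with a median log2 fold change of 1.61 in the authors' deposited table. RPL30, RPS18 and RPL27 were 4.08-fold (3.36 to 4.96), 3.68-fold (3.07 to 4.41) and 3.71-fold (3.06 to 4.51) higher in the authors' deposited table. Ribosomal protein genes share reads with processed pseudogenes, so single values are uncertain. All 32 listed nuclear-encoded respiratory chain genes were higher (adjusted p = 6.33e-09), COX7A2 by 4.14-fold (3.28 to 5.24) in the authors' deposited table. All 16 listed replication-dependent histone genes were higher (adjusted p = 2.01e-04), for example H1-4 by 11.3-fold (7.61 to 16.7) in the authors' deposited table. Another 13 of the 29 histone genes were not listed. Histone genes are near-identical copies whose messages mostly lack a poly(A) tail, so their values are uncertain. Of 15 listed glycolysis genes, 13 were higher (adjusted p = 0.0241), and 8 of the 23 in that list were not listed. GAPDH was 2.39-fold higher (2.05 to 2.78) and HK2 3.03-fold lower (2.45 to 3.76) in the authors' deposited table. PKM, the pyruvate kinase gene on chromosome 15 (72199029 to 72231822), was 1.72-fold higher (1.48 to 2.00) in the authors' deposited table, but with equal implied totals its log2 fold change was 0.39, no longer past the fold threshold. The median mature length was 1074 nt for the ribosomal protein list, 1088 nt for the respiratory chain list, 642 nt for the histones and 2416 nt for glycolysis. Against genes matched on mature length the outcome depended on the reference transcript chosen for each gene. With the principal transcript the adjusted p was 0.00910 for ribosomal proteins, 0.00953 for the respiratory chain and 0.0423 for glycolysis. With the longest coding sequence all 3 calls were lost (adjusted p = 0.110, 0.275 and 0.275). The histone call was lost under both (adjusted p = 0.827 and 0.831), where the matched draws had a median of 93.3% higher. A list with every listed member higher cannot score higher, so for such lists a lost call does not show that length accounts for the rise. By size, the median log2 fold change of the ribosomal protein list in the authors' deposited table, 1.61, lay above length-matched draws with medians of 1.21 to 1.32, past an adjusted p of 0.05 in 7 of 8 matchings (0.0130 to 0.0649). The respiratory chain list, at a median of 1.44 in the authors' deposited table, was past it in 1 (draws with medians of 1.18 to 1.32, adjusted p 0.0317 to 0.583), and glycolysis in 0 (0.617 to 0.979). The histones stood at median percentiles 92.5 and 93.5 of their length deciles under the 2 definitions, with a median log2 fold change of 3.37 in the authors' deposited table against 1.48 for the decile of shortest transcripts. The 15 protein-coding histones lay above the draws in all 4 matchings over all listed genes (permutation test, adjusted p 0.0130 to 0.0260). With a minimum implied mean of 10 in both groups, 9 histones were left, with a median of 1.57 in the authors' deposited table, past the threshold in 0 of 4 matchings (permutation test, adjusted p 0.282 to 0.376). The members left out had an implied control mean below 10, where a fold rests on few reads. The larger median therefore rests on those members. Glycolysis was also not called among genes at least 2-fold changed (adjusted p = 0.428) or with equal implied totals (adjusted p = 0.390).

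**Figure D2:**
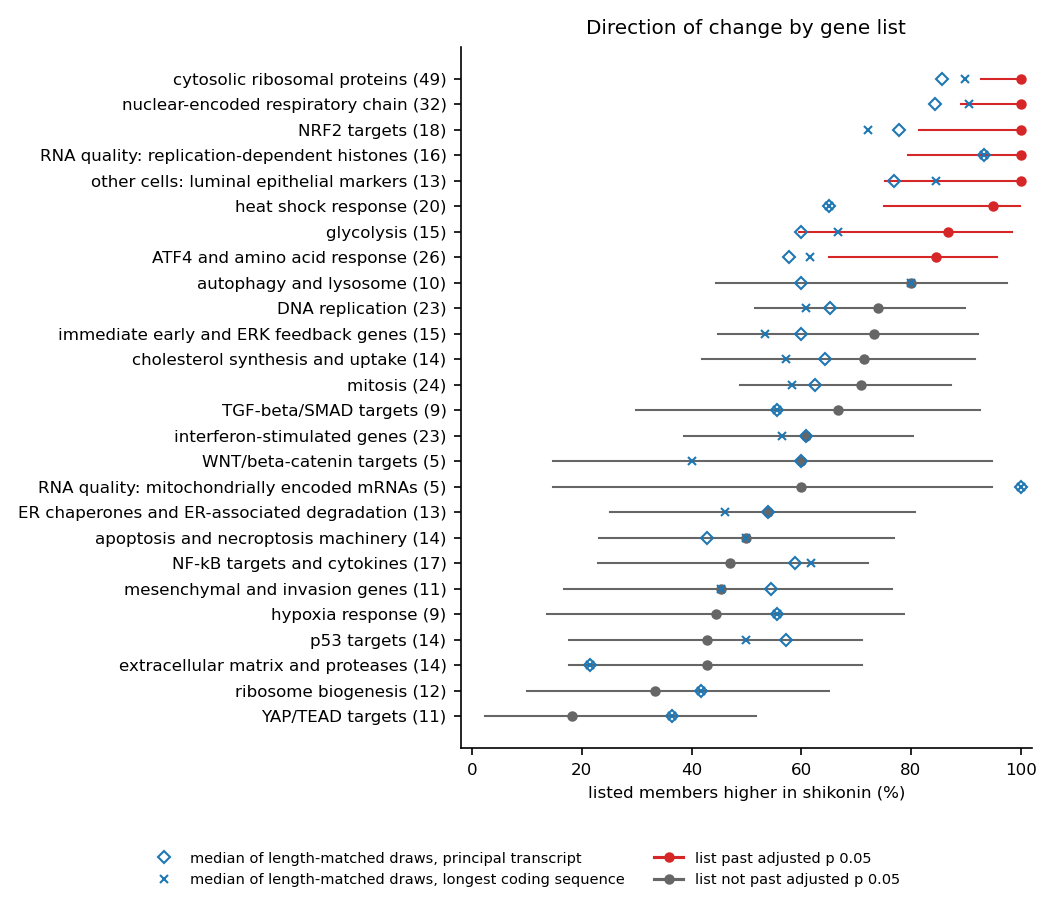
Percent of listed members that were higher in shikonin for the 26 lists tested (number of listed members in brackets), with exact Clopper-Pearson 95% intervals; red marks lists past an adjusted p of 0.05, and blue marks give the median percent higher in 10000 draws of other genes matched on mature length, for 2 choices of reference transcript. All 49 ribosomal protein genes were higher, beside medians of 85.7% and 89.8% in the matched draws.

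Direction followed transcript length across the listed protein-coding genes. Among the 692 genes with the shortest mature transcripts, up to 1085 nt, 97.7% were higher (exact 95% interval 96.3 to 98.7). Among the 692 with the longest, from 8008 nt, 4.48% were higher (3.06 to 6.30). Across 6920 genes, which are not independent replicates, Spearman's rho between mature length and log2 fold change was -0.70. With the length of the transcript that has the longest coding sequence, rho was -0.69. Coding length gave a rho of -0.60, and the length of the 3' untranslated region gave -0.48. For genomic span the shares ran from 89.0% to 15.6%, with a rho of -0.50. RPL30 (575 nt) stood at percentile 80.6 of fold change within its length decile, and GAPDH and PKM at 67.1 and 52.7. HSPA6, ID2 and SNAI1 stood at 100, 99.7 and 99.7, and HMOX1 at 96.1. Of the other NRF2 targets named above, BLVRB stood at 85.1 and TXN at 59.5, so the rise of TXN was near that of other short transcripts.

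**Figure D3:**
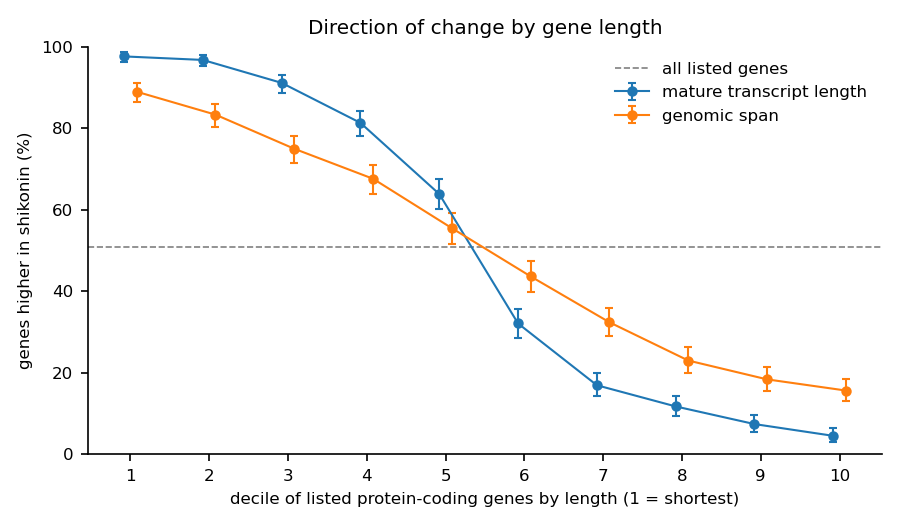
Percent of listed protein-coding genes higher in shikonin in each decile by mature transcript length of the principal transcript (blue) and by genomic span (orange), 692 genes a decile, with exact 95% intervals; the dashed line is the share over all listed genes, 50.8%. The share falls from 97.7% to 4.48% by mature length.

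Genes that fell most firmly were long. LNPEP, which encodes a membrane aminopeptidase, lies on chromosome 5 (96935394 to 97037515) and was 9.09-fold lower (7.50 to 11; adjusted p = 5.97e-110) in the authors' deposited table. PLEC, the gene of the cytoskeletal linker plectin, and TAOK1, a kinase gene, were 7.67-fold (6.11 to 9.62) and 8.51-fold (6.70 to 10.8) lower in the authors' deposited table. FAT1, an atypical cadherin gene, and DICER1, the microRNA-processing nuclease gene, were 9.69-fold (7.23 to 13) and 7.03-fold (5.56 to 8.88) lower in the authors' deposited table. These 5 genes, and HSPA1B above, were named after their values were seen. The principal transcripts of the 5 span 10331 to 15249 nt, within the decile of genes of which 4.48% were higher. NFKBIA, the inhibitor of NF-kB, went against the trend: it has a 1558 nt transcript and was 5.05-fold lower (4.12 to 6.20) in the authors' deposited table. It lies on chromosome 14 from 35401511 to 35404749 and stood at percentile 1.73 of its length decile.

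The other lists, apart from the luminal epithelial markers described below, showed no call in the Fisher test. Among NF-kB targets and cytokines 8 were higher and 9 lower (adjusted p = 0.959): BIRC3 was 4.82-fold lower (3.87 to 5.99) and IL1B 4.23-fold higher (3.42 to 5.24) in the authors' deposited table. For immediate early and ERK feedback genes the split was 11 higher and 4 lower (adjusted p = 0.237), with FOSB 15-fold (12.3 to 18.5) and EGR2 33.0-fold (23.0 to 47.2) higher in the authors' deposited table. By size, that list passed in 0 of 8 length matchings (two-sided permutation test, adjusted p 0.252 to 0.646). Its median of 1.59 nonetheless lay above the highest draw in most of them (1.09 to 1.61). With equal implied totals that list was called (adjusted p = 0.0402). Mesenchymal and invasion genes were 5 higher and 6 lower, TGF-beta/SMAD targets 6 and 3, p53 targets 6 and 8, and apoptosis and necroptosis genes 7 and 7 (adjusted p 0.777 to 1). The size of the median change of p53 targets, -0.88 in the authors' deposited table, was past an adjusted p of 0.05 in 1 of 8 length matchings (0.0317 to 0.248). In a list split 6 and 8 that median rests on which side holds more genes. DNA replication genes were 17 higher and 6 lower (adjusted p = 0.0930), a call reached among genes below an adjusted p of 0.001 (0.0310) and among those with a mean of at least 100 normalized counts (0.0141). With equal implied totals 50% of the DNA replication list was higher (adjusted p = 0.589), and it was not called against genes matched on genomic span (0.253) or mature length (0.646 with the principal transcript and 0.310 with the longest coding sequence). Mitosis genes were 17 higher and 7 lower (adjusted p = 0.152), with CKS2 (613 nt) 3.71-fold higher (3.03 to 4.54) and MKI67 (12678 nt) 4.91-fold lower (3.67 to 6.56) in the authors' deposited table. YAP/TEAD targets were 2 higher and 9 lower (adjusted p = 0.0930), and their median mature length was 5507 nt. Cholesterol genes were 10 and 4 (adjusted p = 0.334, and 0.0478 among genes at least 2-fold changed), autophagy and lysosome genes 8 and 2 (0.237), and ribosome biogenesis genes 4 and 8 (0.450). ER chaperone and degradation genes were 7 and 6, interferon-stimulated genes 14 and 9, hypoxia genes 4 and 5, extracellular matrix genes 6 and 8, and WNT targets 3 and 2 (adjusted p 0.659 to 1). The median of the ER list, 1.09 in the authors' deposited table, was past an adjusted p of 0.05 in 4 of 8 length matchings (0.0130 to 0.123), but in a list split 7 and 6 the median rests on which side holds 1 gene more. AHR targets (1 higher, 2 lower) and metallothioneins (2 higher, 1 lower) had fewer than 5 listed members and were not tested.

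Listed markers of other cell types were higher, while the mitochondrially encoded messages, kept as markers of RNA quality, were split. All 13 listed luminal epithelial markers, of 20 in the list, were higher (adjusted p = 0.00107). KRT18 was 3.18-fold (2.61 to 3.87) and CLDN7 3.60-fold (2.88 to 4.51) higher in the authors' deposited table. Their call was lost against genes matched on mature length (adjusted p = 0.111 with the principal transcript and 0.310 with the longest coding sequence) and on genomic span (0.0717), with every member higher. By size they stood at median percentiles 83.4 and 82.5 of their length deciles under the 2 definitions. Their median log2 fold change in the authors' deposited table, 1.78, lay above length-matched draws with medians of 0.90 to 1.11, past an adjusted p of 0.05 in 7 of 8 matchings (0.0130 to 0.0649). The 4 listed blood and immune markers and the 3 listed fibroblast and endothelial markers were all higher and too few to test. Most members of these lists were not listed: 15 of 19 blood and immune markers and 12 of 15 fibroblast and endothelial markers. With equal implied totals CD68 and PDGFRB were no longer past the thresholds. Of 5 listed mitochondrially encoded messages, of 13 in the list, 3 were higher and 2, MT-ND6 and MT-ATP8, lower (adjusted p = 1). Against length-matched genes, whose median draw was 100% higher, that list was called toward lower with the principal transcript (adjusted p = 0.0217) and not with the longest coding sequence (0.0715). By size, its median of 0.80 in the authors' deposited table lay below matched draws with medians of 1.45 to 1.73, past the threshold in 6 of 8 matchings over both definitions (permutation test, adjusted p 0.0130 to 0.123). MT-ND6 lies opposite other messages of the circular genome, and MT-ATP8 overlaps MT-ATP6, so both are uncertain.

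The genes with the most extreme listed folds mostly had a group with almost no reads. Besides HSPA6, the 5 most increased named by the rule were CRYAB, LOC284344, KRT18P17, OVOL1 and LCK, each with an implied control mean below 1 normalized count. The 6 most decreased were INTS3, ARHGEF18, PRORP, LOC100419515, CCDC65 and NAIP, each with an implied shikonin mean below 1. No fold is given for them, because it rests on the fit at a mean near 0. In all, 168 listed genes had such a group, 153 of them higher and 15 lower.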

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

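Every alternative here was chosen after seeing the data, because none of the planned ones (scaling, filter, tool, pseudocount, centring, correlation, block or leaving out a library) could be run on a table without per-sample values. No paired analysis was possible because the table carries no sample or replicate columns. Of the 7150 listed genes, 4428 remained at a fold change of at least 2. Of those, 2235 had a fold interval wholly beyond 2-fold. Of the 8 lists called, 5 were called when matched on genomic span and 3 when matched on the mature length of the longest coding sequence. Matching on that of the principal transcript called 7: 6 of the 8, without the histones and luminal markers, and the mitochondrially encoded messages, toward lower. The calls by share left under all 3 matchings were those of NRF2 targets and the ATF4 response. By size of the median change against length-matched draws the ATF4 response passed in 0 of 8 matchings (adjusted p 0.0891 to 0.251) and NRF2 targets in 8. That difference depends on the two-sided count, in which draws with a negative median counted as far off as a rise. Over all listed genes the ATF4 median lay above the highest draw in most matchings, and the NRF2 median did not. By share, the choice of transcript decided the length-matched calls of the ribosomal protein, respiratory chain and glycolysis lists, and the cause was not tested further. By size, the ribosomal protein list passed in 7 of 8 matchings over both choices, though the matchings reuse largely the same genes. The other filters and the scaling kept 7 or 8 of the 8 and each called 1 more. With equal implied totals, 117 named genes stayed past the thresholds and 5 (CYP1A1, MT-ND2, CD68, PDGFRB and PKM) did not; that shift, 0.39, is below the smallest listed change, 0.59, so it could reverse no gene. Library depth is unknown, so its limits cannot be stated.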

Other observations

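All tests of the length pattern, the length test of the luminal markers, the tests of the size of a rise and the comparison of 3 lists with other genes were chosen after the results were seen; the other tests below were set before. A few long genes rose against the trend, chosen after their values were seen. CAMTA1, a calmodulin-binding transcription activator gene with an 8444 nt transcript, was 3.83-fold higher (2.90 to 5.06) in the authors' deposited table. ARID5B and LAMA2, a chromatin regulator and a laminin chain gene, were 4.07-fold (3.02 to 5.48) and 6.55-fold (4.02 to 10.7) higher in the authors' deposited table, at percentiles 98.3 and 98.8 of their length deciles. Single-exon genes were higher in 55.1% of 118 cases and multi-exon genes in 50.3% (two-sided Fisher exact p = 0.308). Length-matched draws of multi-exon genes had a median of 64.4% (range 54.2 to 73.7), so the single-exon share lay near their lower end.

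Short transcripts were mostly higher and long ones lower, and genomic span alone, as slower transcription through long genes would give, is argued against: within deciles of span the shortest and longest tertiles by mature length still differed by 54.5 percentage points (95% bootstrap interval 52.0 to 56.3). GC content alone is argued against in the same way, with 52.3 points between tertiles by span within GC deciles (49.9 to 54.7). A version by the length of the 3' untranslated region was run once and left out. No such result is given here for that length or for coding length. Mature length alone, as RNA breakage or size selection would give, stays open: within its deciles the tertiles by span differed by 10.2 points (8.57 to 12.7), beside -0.24 in simulated tables with directions set by mature length only and 41.5 with span only. The simulation with mature length only held the share constant within each decile, so it could leave no difference by span. In the data the share fell from 63.9% in decile 5 to 32.1% in decile 6, and span rose with mature length (Spearman's rho 0.61). Differences in length within deciles and errors in the annotated lengths, neither simulated, could therefore also give the 10.2 points. An effect of shikonin on long transcripts cannot be told apart from a difference in RNA integrity between the groups, as every shikonin library is treated and no integrity value is held.

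Ribosomal protein, respiratory chain and histone genes rose together. Their median log2 fold change lay 0.98 above that of the other listed genes (95% bootstrap interval 0.91 to 2.27). Scaling between groups cannot be tested by this difference, since 1 factor moves every gene alike. A positive difference was also assured, because the 3 lists were compared after all their members were seen to be higher. Its size is uncertain: the median of the other genes, 0.59, lay at the smallest listed change. With the other genes split almost evenly, that median rests on which side holds more genes. For the rise itself scaling stays open, since 100% of the 97 listed members stayed above 0 with equal implied totals, but that shift of 0.39 is below the smallest listed change, 0.59, so the outcome was fixed. Short transcripts favoured in the shikonin libraries stay open for the histones. The median of the 15 protein-coding histones, 3.25, lay above the highest length-matched draw, 3.18, but this bound was changed and set back after results were seen. With implied means of at least 10 in both groups, the median of the 9 histones left, 1.57, lay within the draws (highest 2.11). Favoured short transcripts also stay open for the other 2 lists. The ribosomal protein median of 1.61 lay above the medians of the length-matched draws but not above every draw (highest 1.70). The draws take these co-regulated genes as independent, so they do not decide whether length is the whole cause. The respiratory chain median of 1.44 lay within the draws (highest 1.68). By share higher, the draws matched to the 3 lists reached 93.8%, so that the bound set before, 10 points above them, could not be passed. A change in polyadenylated RNA capture in the shikonin libraries stays untested, as 0 structured small RNA genes were listed.

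Luminal epithelial markers lay on the higher side in this mesenchymal line. Short transcripts favoured in the shikonin libraries stay open: length-matched draws had a median of 76.9% higher, a share that reached its limit and decides nothing. The size of the rise, a median of 1.78, lay above the medians of the draws (permutation p at most 0.00999) but not above every draw (highest 1.88). Those draws hold falling genes, which lowers their medians, and take genes as independent. The size therefore does not decide whether length is the whole cause. A general rise of genes with a low level in the control stays open, since draws matched on control mean reached 100%, so that the bound set before could not be passed, although their median was 61.5% (two-sided permutation p = 0.00899), which counts against it. That p-value also takes genes as independent and is too small. Cells of another type in the shikonin libraries also stay open: 5 of the 13 markers had an implied shikonin mean in the top decile of listed genes, but 4 of these were already in the top decile in control, so this decides nothing. A response of the cells to shikonin was not tested separately.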
